A study of Mus musculus with 12 samples.

How the data were processed

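Gene expression was measured in macrophages taken from aortic plaques of LDLR knockout mice on 12 Affymetrix mouse genome arrays, 4 per group. Per the labels, biotin-labelled cRNA made from total RNA was hybridised. The treatments were anti-miR-33, a control anti-miR or saline, the last group being titled untreated but described as saline. The deposited table holds log2 values for 45101 probe sets, summarised by RMA per the submitters' processing notes, which give no version. RMA corrects background, normalises between arrays and combines the probes of a probe set on a log2 scale. The log2 base was read from the values, which lay between 2.16 and 14.96. Array medians lay between 6.84 and 6.96, so arrays were on a common scale and genes were not centred, but the settings of the normalisation stay unknown. Correlations between arrays ranged from 0.962 to 0.987, and no array repeated another's values. Scanner images and intensities of single probes were not used here. The number of arrays limits the precision of every difference.

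The probe annotation given for this series named 1 gene symbol for 34958 probe sets, several symbols for 932 and none for 9211. Entrez identifiers of 34754 of the one-symbol probe sets were found in the RefSeq gene table, and the update changed 0 symbols. Probe sets with several symbols were left unnamed. The named probe sets covered 18194 genes.

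Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) on the deposited log2 values of all 12 arrays, with 3 groups, no covariate and no filter on dim probe sets. P-values were two-sided and adjusted by Benjamini-Hochberg over 45101 probe sets, with a threshold of 0.05. The comparisons were anti-miR-33 against control anti-miR, anti-miR-33 against saline, control anti-miR against saline, and anti-miR-33 against the mean of both control groups. Per the labels each array is 1 biological replicate, and the design text gives 4 animals per group. P-values therefore measure the spread between these arrays, as no source used here ties an array to an animal or says how captured regions were chosen.

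Of 33 gene lists, 32 had at least 4 measured members and were tested. The erythroid list had 3 of 6 members measured and was left out. A list was tested by limma's camera with a preset inter-gene correlation of 0.01, two-sided, on the probe set of highest mean for each gene, and adjusted over the 32 lists. An estimated correlation and fry were run beside it. Fry tests whether a list's genes move one way on balance and does not compare the list with other genes. List means per array were compared by exact two-sided permutation tests, whose smallest p with 4 against 4 arrays (70 arrangements) is 0.0286. The members of each list, the tests, the comparisons and the rule for named genes were fixed before the data were examined.

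The genes named were, per comparison, the 10 with the largest rise and the 10 with the largest fall among probe sets past the threshold. Where none passed, they were the 10 of smallest unadjusted p in each direction, given as not past the threshold. A gene with several probe sets is represented by the one that met this rule, and values of its other probe sets are not given. Up to 4 members of each list with the smallest p were added, with a fixed set that includes Abca1, Abcg1, Npc1, Cpt1a, Crot, Hadhb, Prkaa1, Srebf2, Arg1, Nos2, Tnf, Tlr4, Ccr7 and Cd68. The exceptions, which were chosen after their values were seen, are Xist, Eif2s3y, Kdm5d, Uty, the pigment cell genes, the tissue-resident macrophage genes, the other list members that passed over the list alone, Myl2, Acta1 and the cell type markers quoted for their level. Unnamed transcripts were not quoted. Ldlr had 0 probe sets named for it alone in the annotation and was not analysed here. A test of genes with miR-33 seed sites was not run, as 3' untranslated regions were not used here.

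The limma and camera steps were tested on simulated data made from the real means and spreads of 45101 probe sets, with 67 probe sets changed 2-fold, 67 changed 4-fold and 66 changed 8-fold. For anti-miR-33 against control anti-miR, 44.8% of 2-fold, 86.6% of 4-fold and 98.5% of 8-fold changes were recovered, with 12 false calls. For that comparison a shift of 0.5 added to the fatty acid oxidation list gave a camera adjusted p of 3.35e-14, with 0 other lists past the threshold. With the same shift 1 other list passed for anti-miR-33 against saline, and 0 did in the remaining comparisons. Probe sets were drawn independently of each other. The simulations therefore do not show how often camera calls lists of correlated genes without a change. The shares of changes recovered were 40.3%, 91% and 93.9% for anti-miR-33 against saline, with 11 false calls. They were 50.7%, 88.1% and 95.5% for control anti-miR against saline, with 10, and 64.2%, 92.5% and 98.5% for anti-miR-33 against both control groups, with 9.

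Alternatives covered a second quantile normalisation, centring on array medians, only probe sets above the 40th percentile of mean signal, eBayes without trend or with a robust fit, array weights, only the groups compared, an adjusted p threshold of 0.1, the replicate number as a block, the mean of all probe sets of a gene, and leaving out each array in turn. A covariate for expression-defined sex and a fit of the 9 arrays with Xist signal were added after the data were seen.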

Results

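Macrophages were captured by laser microdissection from aortic plaques of LDLR knockout mice, a strain that lacks the LDL receptor and develops atherosclerosis on a high-fat diet. Mice were weaned at 4 weeks and given a diet with 21% fat and 0.3% cholesterol for 14 weeks, then chow for 4 weeks. During those 4 weeks they received anti-miR-33, an oligonucleotide that blocks the microRNA miR-33, or a control anti-miR, both at 10 mg/kg, or saline, with 2 injections in the first week and weekly injections after it. The third group is called untreated in its sample titles but saline in its sample descriptions and in the study design, and is called saline here. Each group had 4 arrays, labelled as biological replicates. Values are RMA log2 signals, given as mean ± SD with n = 4 arrays per group unless stated. Differences are log2 differences ± SE from limma.

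The captured material gave signal for genes of macrophages and of other cell types. Signals of different probe sets also depend on their probes, so these levels do not rank the cell types. Cd68, a lysosomal protein of macrophages, had a mean of 12.94 ± 0.19 over 12 arrays. Lyz2, the macrophage lysozyme, was at 14.39 ± 0.10. The heart muscle genes Myh6 and Myl7 were at 13.74 ± 0.38 and 13.42 ± 0.53. Dcn and Col3a1, matrix genes of fibroblasts, reached 14.30 ± 0.12 and 14.18 ± 0.09, Acta2, the smooth muscle actin, 14.04 ± 0.14, and Comp, a cartilage matrix gene, 12.77 ± 0.56. The 3' minus 5' difference of the control probe sets, a measure of RNA degradation, was 1.52 ± 0.23, 1.54 ± 0.15 and 1.55 ± 0.17 for Actb with anti-miR-33, control anti-miR and saline. For Gapdh it was 1.45 ± 0.16, 1.67 ± 0.22 and 1.66 ± 0.45. No pair of groups differed in either measure by more than the spread between arrays (exact permutation p from 0.171 to 1).

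Sex-linked genes split the arrays, all 12 of which are labelled male. Values are those of the brightest probe set of each gene. On 9 arrays Xist, the RNA that silences an X chromosome in female cells, was at 13.20 to 13.74, while the Y-linked genes Eif2s3y, Kdm5d and Uty were at 2.42 to 4.10. On the other 3 arrays, anti-miR-33 replicate 4 and saline replicates 1 and 3, Xist was at 5.76 to 6.80, Eif2s3y at 12.03 to 12.30, Kdm5d at 9.14 to 9.56 and Uty at 7.74 to 9.42. Arrays with Xist signal numbered 3 of 4 with anti-miR-33, 4 of 4 with control anti-miR and 2 of 4 with saline. No array had both Xist and the mean of the Y-linked genes above the median of all values, 6.90, or neither.

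**Figure D1:**
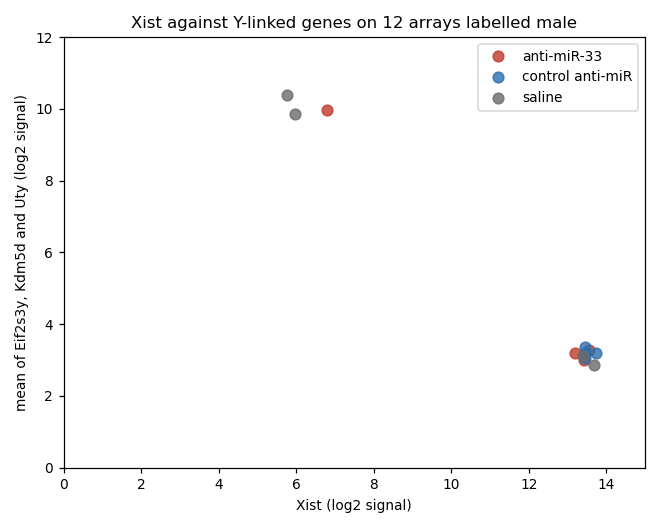
Xist signal (x axis, log2) against the mean log2 signal of the Y-linked genes Eif2s3y, Kdm5d and Uty (y axis) on 12 arrays labelled male, 1 point per array, coloured by group. The 9 arrays with Xist at 13.20 to 13.74 lie apart from the 3 arrays with Xist at 5.76 to 6.80.

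Anti-miR-33 was compared with control anti-miR to ask how blocking miR-33 changes gene expression in plaque macrophages. Inflammatory genes were lower with anti-miR-33. The M1-type list, genes of classically activated macrophages, fell by 0.74 on average, from 8.68 ± 0.26 to 7.94 ± 0.25, and 19 of its 20 members were lower. Cxcl9 (-3.16 ± 0.96) and Cxcl10 (-2.10 ± 0.55), chemokines induced by interferon that attract T cells, and Ccl5 (-1.65 ± 0.36), Cd86 (-1.23 ± 0.25), a costimulatory receptor, and Tnf (-0.85 ± 0.24) passed when adjusted over the list alone, 5 in all, and none passed over all probe sets. The list's adjusted p was 6.78e-06 by limma's camera, adjusted p = 0.165 with an estimated correlation and 0.0297 by fry. Over 21 alternatives it ran from 5.71e-07 to 0.165.

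Interferon-stimulated genes fell by 0.59, with 16 of 16 members lower and Cxcl10 alone past the test adjusted over the list alone (camera adjusted p = 4.06e-05, and adjusted p = 0.399 with an estimated correlation). T cell markers moved with these groups. They fell by 1.02, from 8.91 ± 0.74 to 7.89 ± 0.16, with 8 of 8 members lower (camera adjusted p = 6.01e-05, and adjusted p = 0.255 with an estimated correlation). Cd8a (-1.95 ± 0.51), Cd3d (-1.68 ± 0.47) and Cd3e (-1.10 ± 0.31), parts of the T cell receptor complex and its coreceptor, passed when adjusted over the list alone. Macrophage markers fell by 0.29, with 14 of 14 lower, among them Fcgr1 (-0.76 ± 0.28) and Csf1r (-0.21 ± 0.08), though none passed when adjusted over the list alone, at a camera adjusted p of 3.5e-04, against adjusted p = 0.358 with an estimated correlation. Adhesion and migration genes fell by 0.36, including the integrins Itgal (-0.90 ± 0.29) and Itgb2 (-0.50 ± 0.17), neither past the test adjusted over the list alone, at a camera adjusted p of 0.00439, against adjusted p = 0.165 with an estimated correlation. With the mean of all probe sets of a gene their shift was -0.23, still past the threshold.

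Genes that burn fatty acids were higher. The fatty acid oxidation list rose by 0.37, from 10.60 ± 0.05 to 10.97 ± 0.20, with 18 of 19 members higher (camera adjusted p = 4.39e-08, and adjusted p = 0.165 with an estimated correlation). Fry gave 0.048, and over 21 alternatives the adjusted p ran from 1.05e-08 to 0.165. Ppara (0.92 ± 0.27), the nuclear receptor that induces these enzymes, Etfdh (0.65 ± 0.16), Acadl (0.52 ± 0.17) and Acadm (0.39 ± 0.11) passed when adjusted over the list alone, and none did over all probe sets. Oxidative phosphorylation genes rose by 0.15, with 72 of 94 higher and 0 past the test adjusted over the list alone (camera adjusted p = 1.01e-06, and adjusted p = 0.497 with an estimated correlation). The rise was 0.08 without anti-miR-33 replicate 3. Heart muscle markers moved the same way. The cardiac and skeletal muscle list rose by 0.50 (camera adjusted p = 8.43e-06, and adjusted p = 0.345 with an estimated correlation). In that list 7 of 9 members passed when adjusted over the list alone, among them Ryr2 (1.07 ± 0.27), Myl7 (0.90 ± 0.23), Actc1 (0.81 ± 0.24) and Tnnt2 (0.68 ± 0.20), while Myl2 (-0.73 ± 0.73) and Acta1 (-0.40 ± 0.67) did not. Smooth muscle markers rose by 0.43, with 9 of 10 members higher, at a camera adjusted p of 1.18e-04, against adjusted p = 0.358 with an estimated correlation.

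**Figure D2:**
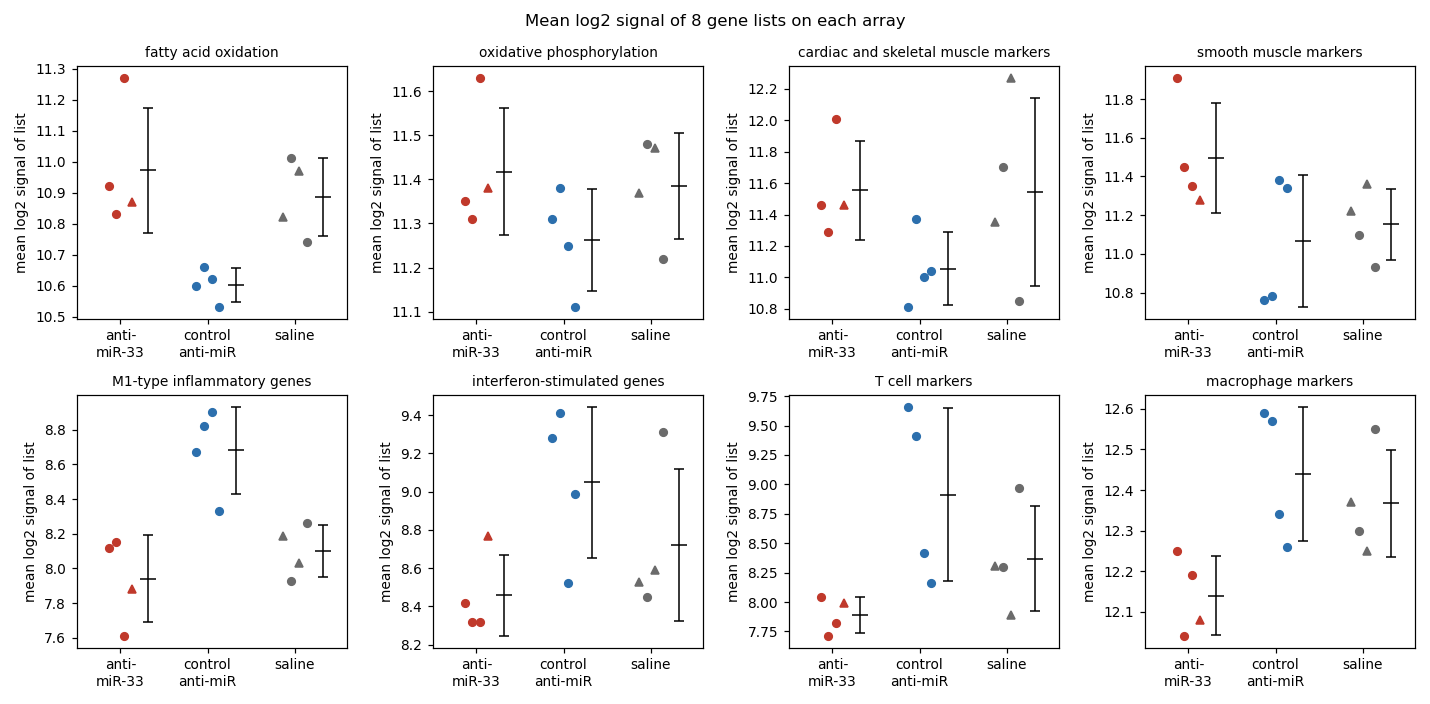
Mean log2 signal of 8 gene lists (y axis) on each array, by group (x axis), with triangles for the 3 arrays with Y-linked signal, circles for the 9 with Xist signal and the mean ± SD of 4 arrays in black. The M1-type means of the 4 control anti-miR arrays lie above those of the other 8 arrays, and their fatty acid oxidation means lie below.

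Cholesterol export genes did not rise in the captured material. Macrophage markers fell by 0.29 in the same comparison, so these signals do not show the level per macrophage. Abca1, which exports cholesterol and is a published miR-33 target, was at 13.32 ± 0.06 with anti-miR-33 and 13.45 ± 0.11 with control anti-miR (-0.13 ± 0.08), and Abcg1 at 13.12 ± 0.07 and 13.36 ± 0.10 (-0.24 ± 0.08), with limma adjusted p of 0.756 and 0.523. The efflux and LXR list fell by 0.17, with 11 of 13 members lower, among them Apoc2 (-0.79 ± 0.27), and none past the test adjusted over the list alone. Its camera adjusted p was 0.027, against adjusted p = 0.449 with an estimated correlation, and the call was lost without anti-miR-33 replicate 4 (-0.15), control anti-miR replicate 1 (-0.16) or control anti-miR replicate 4 (-0.19), and on the 9 Xist arrays (-0.15). The 27 published miR-33 targets had a mean difference of 0.06 and a median of -0.04, of opposite sign, and did not differ from other genes (camera adjusted p = 0.649). Ppargc1a (1.50 ± 0.48) and Osbpl6 (0.89 ± 0.36) stood above Npc1 (-0.24 ± 0.13), Cpt1a (0.04 ± 0.17), Crot (-0.23 ± 0.23), Hadhb (0.29 ± 0.12), Prkaa1 (-0.40 ± 0.36), Atg5 (-0.70 ± 0.31) and Ccnd1 (-0.46 ± 0.17), and none of the 27 passed when adjusted over the list alone. Osbpl6 differed by 0.53 without anti-miR-33 replicate 3. Srebf2, whose intron holds miR-33, differed by 0.18 ± 0.17.

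Among the other lists that passed, MHC class II genes fell by 0.36 (camera adjusted p = 0.00594, and adjusted p = 0.497 with an estimated correlation), a call lost without anti-miR-33 replicate 1 (-0.24) or control anti-miR replicate 2 (-0.19). Fibroblast markers rose by 0.16 (camera adjusted p = 0.027, and adjusted p = 0.416 with an estimated correlation). That call was lost without anti-miR-33 replicate 2 (0.17), anti-miR-33 replicate 4 (0.12) or control anti-miR replicate 2 (0.17), on the 9 Xist arrays (0.12) and without dim probe sets (0.16). Neutrophil markers fell by 0.57 (camera adjusted p = 0.0312, and adjusted p = 0.238 with an estimated correlation). Without anti-miR-33 replicate 2 (-0.55), anti-miR-33 replicate 4 (-0.44), control anti-miR replicate 3 (-0.42) or control anti-miR replicate 4 (-0.58) they did not pass, nor with sex as a covariate (-0.55) or on the 9 Xist arrays (-0.44). Of the neutrophil markers, S100a8 (9.67) and S100a9 (8.72) had means over 12 arrays above the median of all values, 6.90. Elane, Mpo, Cxcr2, Camp, Ngp and Ltf had means of 4.00 to 6.26, so their part of the fall may be background. Chondrocyte markers rose by 0.61 (camera adjusted p = 0.0476, and adjusted p = 0.559 with an estimated correlation). This call was lost without anti-miR-33 replicates 1 (0.66), 2 (0.52) or 4 (0.43), control anti-miR replicates 1 (0.46) or 2 (0.27), or saline replicates 1 or 4 (0.61 in both), and the shift was 0.95 without control anti-miR replicate 3. It was also lost with a second quantile normalisation (0.61), without dim probe sets (0.61), with the mean of all probe sets of a gene (0.55), with sex as a covariate (0.44) and on the 9 Xist arrays (0.43).

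The remaining 18 lists, the miR-33 targets among them, did not pass. M2-type genes differed by -0.25, though Cd163 (1.49 ± 0.40), a scavenger receptor, was higher and Chil3 (-1.81 ± 0.51) and Il10 (-1.67 ± 0.51) lower, all past the test adjusted over the list alone. Among control anti-miR arrays, replicate 4 had a lower M2-type mean (8.16) than the others (8.86 to 8.96). Mean differences were -0.28 for dendritic cell markers, -0.23 for lipid uptake and storage, -0.14 for efferocytosis, -0.10 for lysosome and autophagy, -0.11 for Toll-like receptor signalling, -0.17 for matrix remodelling, -0.10 for the unfolded protein response, -0.13 for cell cycle, -0.11 for cholesterol synthesis and -0.02 for ribosomal proteins. They were 0.18 for immediate early genes, 0.03 for glycolysis, 0.11 for endothelial, 0.17 for B cell, -0.23 for mast cell and 0.68 for adipocyte markers. Camera's adjusted p for these ran from 0.0609 to 0.942.

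By gene, Ptpn6, the phosphatase SHP-1 of blood cells, had the smallest adjusted p (-1.16 ± 0.15, limma adjusted p = 0.185). It was at 9.28 ± 0.15, 10.43 ± 0.09 and 9.56 ± 0.19 with anti-miR-33, control anti-miR and saline. Other genes low with anti-miR-33 were Gpr18 (-2.14 ± 0.32), Ifi209 (-1.83 ± 0.28), Ipcef1 (-1.41 ± 0.26), Cd8b1 (-1.37 ± 0.24), Dennd1c (-1.12 ± 0.21), Fes (-1.07 ± 0.19), Galnt7 (-1.01 ± 0.17), Sla (-0.84 ± 0.16) and Basp1 (-0.45 ± 0.08). Genes high with it were Mlana (2.57 ± 0.42), a melanosome gene, Cxcl13 (2.47 ± 0.48), a B cell chemokine, Klhl30 (1.52 ± 0.31), Aif1l (1.46 ± 0.25), Vstm4 (1.27 ± 0.25), Prkaa2 (1.25 ± 0.24), Ablim3 (1.09 ± 0.23), Ikzf4 (0.99 ± 0.20), Rcan2 (0.71 ± 0.14) and Hadh (0.42 ± 0.08). Cd8b1 and Aif1l were below the median of all values, 6.90, on all arrays. Nos2 (-0.32 ± 0.21), Arg1 (-0.16 ± 0.40), Tlr4 (-0.04 ± 0.28), Ccr7 (-0.66 ± 0.37) and Cd68 (-0.23 ± 0.12) were within 2 SE of no difference. In limma 0 probe sets passed an adjusted p of 0.05, and 3328 had an unadjusted p under 0.05, 1570 higher and 1758 lower, where chance gives 2255. Camera called 14 of 32 lists, 6 up and 8 down, against 0 with an estimated correlation and 4 with fry. Exact permutation tests of the list means gave p under 0.05 for 6 lists and 0 after adjustment.

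Anti-miR-33 was next compared with saline. Smooth muscle markers were higher and macrophage and M2-type genes lower with anti-miR-33. Smooth muscle markers rose by 0.35, with 10 of 10 members higher, including Lmod1 (0.54 ± 0.24), at a camera adjusted p of 2e-04, against adjusted p = 0.77 with an estimated correlation. The rise was 0.21 without anti-miR-33 replicate 1 and 0.56 on the 9 Xist arrays. M2-type genes, linked to alternative activation, fell by 0.40 (camera adjusted p = 0.00446, and adjusted p = 0.77 with an estimated correlation), with 18 of 20 lower and differences of -1.49 ± 0.51 for Chil3, -0.97 ± 0.40 for Arg1 and -0.91 ± 0.34 for Pdcd1lg2. The Arg1 difference was -0.54 without saline replicate 4 and -1.54 on the 9 Xist arrays, that of Pdcd1lg2 was -0.60 without saline replicate 2, and that of Chil3 was -0.85 on the 9 Xist arrays. Macrophage markers fell by 0.23, with 14 of 14 lower (camera adjusted p = 0.00958, and adjusted p = 0.77 with an estimated correlation). The M2-type and macrophage calls were each lost without anti-miR-33 replicate 4 (-0.37 and -0.21) or saline replicate 4 (-0.32 and -0.17). No member of these lists passed when adjusted over the list alone.

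The lists that led the previous comparison were closer to saline. M1-type genes differed by -0.16, fatty acid oxidation by 0.09, oxidative phosphorylation by 0.03, T cell markers by -0.48, interferon-stimulated genes by -0.26 and cardiac and skeletal muscle markers by 0.02, with camera adjusted p from 0.079 to 0.39. Single saline arrays weigh on some of these. Saline replicate 4 was high for interferon-stimulated genes (9.31, others 8.45 to 8.59) and T cell markers (8.97, others 7.89 to 8.31). Saline replicate 3 was high for cardiac and skeletal muscle markers (12.27, others 10.85 to 11.70). Abca1 differed by -0.12 ± 0.08, Abcg1 by -0.16 ± 0.08 and Tnf by -0.60 ± 0.24. The genes of smallest p were lower for Ryr1 (-1.48 ± 0.27), a muscle calcium channel, Pclaf (-1.38 ± 0.32), Sfxn2 (-1.27 ± 0.28), St18 (-1.22 ± 0.28), Pctp (-1.06 ± 0.20), Igsf6 (-0.94 ± 0.20), Pkib (-0.83 ± 0.16), Foxd2 (-0.80 ± 0.18), Btbd19 (-0.75 ± 0.15) and Rmdn2 (-0.50 ± 0.11). They were higher for Elavl1 (1.44 ± 0.34), Mettl22 (1.30 ± 0.30), Aif1l (1.05 ± 0.25), Lman2l (0.96 ± 0.23), Pde5a (0.95 ± 0.25), Plxna4 (0.90 ± 0.24), Kdm5b (0.82 ± 0.19), Rab3d (0.79 ± 0.20), Prkce (0.71 ± 0.18) and Ncam1 (0.45 ± 0.12, and 0.26 on the 9 Xist arrays). None passed. Rmdn2 lay at 2.83 to 3.70 on all arrays, as low as the Y-linked genes on Xist arrays, so its difference may be background. Pclaf, Elavl1, Mettl22, Aif1l and Rab3d were below the median of all values, 6.90, on all arrays. In limma 0 probe sets passed the adjusted threshold (smallest adjusted p 0.997). An unadjusted p under 0.05 was found for 1848, 851 higher and 997 lower, fewer than the 2255 that chance gives. The count of 1848 became 3491 with array weights and 2813 on the 9 Xist arrays, and 1198 among the probe sets left without dim ones.

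Camera called 3 of 32 lists, with 0 by an estimated correlation, 0 by fry, and exact p under 0.05 for 1 list mean (0 after adjustment). The count was 8 without anti-miR-33 replicate 1, 6 without anti-miR-33 replicate 2, 8 without saline replicate 2, 11 without saline replicate 3, 1 without saline replicate 4 and 13 on the 9 Xist arrays, so it depended on which arrays were kept.

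Control anti-miR was compared with saline to show what the control oligonucleotide gives without the miR-33 sequence. Cxcl13, the B cell chemokine, had the largest gap among the genes named, at 7.18 ± 0.19 with control anti-miR, 11.03 ± 0.95 with saline and 9.64 ± 0.90 with anti-miR-33, a difference of -3.85 ± 0.48. Cd163 (-2.11 ± 0.40) and Vsig4 (-1.91 ± 0.31), scavenger and complement receptors of macrophages, were also low with control anti-miR. None of these passed in limma (adjusted p = 0.118 for Cxcl13). Without saline replicate 4, Cxcl13 (-4.31) and Vsig4 (-2.23) did pass, and without dim probe sets Cxcl13 alone did (-3.85).

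**Figure D3:**
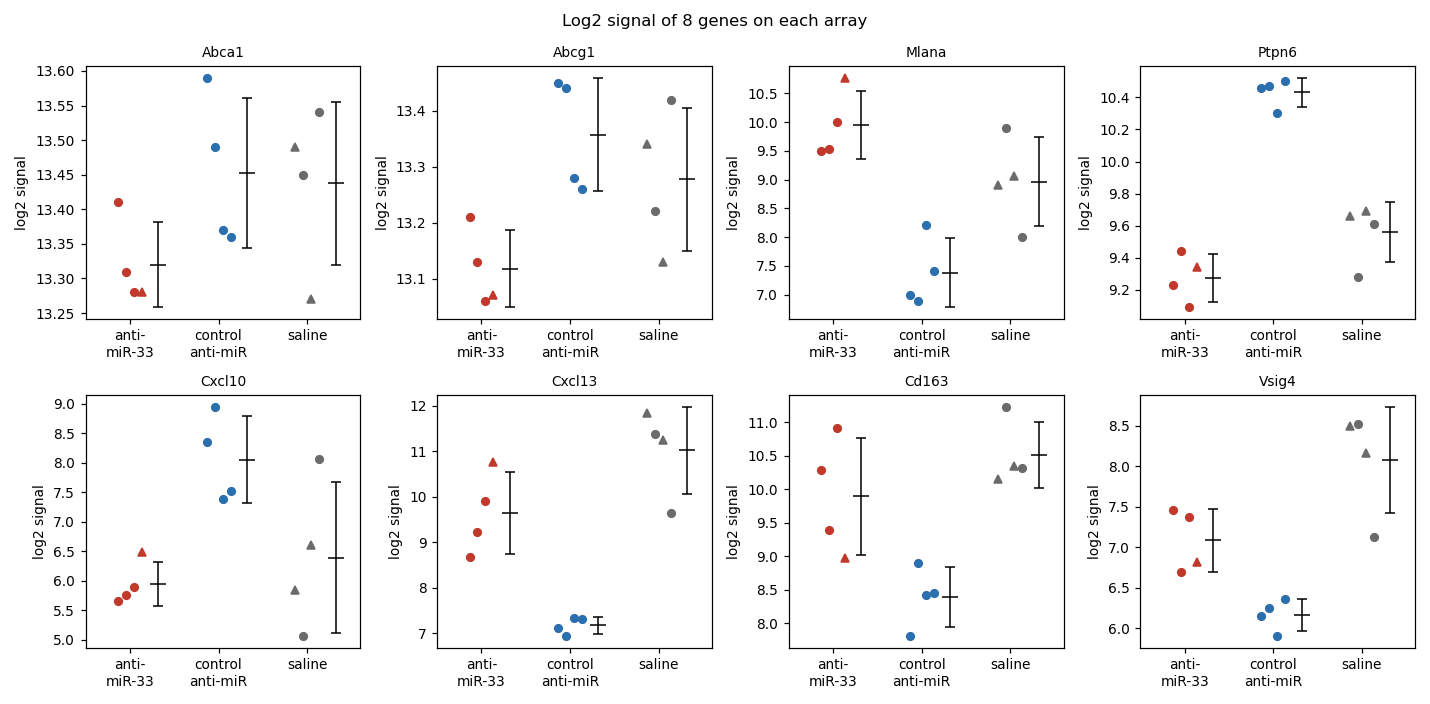
Log2 signal of 8 genes (y axis) on each array, by group (x axis), with the mean ± SD of 4 arrays in black, triangles for arrays with Y-linked signal and circles for arrays with Xist signal. Cxcl13 is at 7.18 ± 0.19 on the control anti-miR arrays, and Abca1 and Abcg1 are no higher with anti-miR-33 than in the other groups.

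M1-type genes rose by 0.58 with control anti-miR, from 8.10 ± 0.15 to 8.68 ± 0.26, with 17 of 20 higher, among them Cxcl10 (1.66 ± 0.55), Ccl5 (0.98 ± 0.36), Cd86 (0.69 ± 0.25) and Nos2 (0.58 ± 0.21). None of the 20 passed when adjusted over the list alone. The camera adjusted p was 6.23e-06, against adjusted p = 0.152 with an estimated correlation, and over 21 alternatives it ran from 2.23e-06 to 0.198. Fatty acid oxidation genes fell by 0.28, with 17 of 19 lower (camera adjusted p = 1.9e-05, and adjusted p = 0.406 with an estimated correlation). Ppara (-0.98 ± 0.27) and Acadm (-0.48 ± 0.11) passed when adjusted over the list alone, and neither did over all probe sets. Heart muscle markers fell beside them. The cardiac and skeletal muscle list fell by 0.49, with Ryr2 (-0.85 ± 0.27) and Myl7 (-0.73 ± 0.23) past the test adjusted over the list alone (camera adjusted p = 5.85e-05, and adjusted p = 0.476 with an estimated correlation). Its shift was -0.24 without saline replicate 3, and the call was lost on the 9 Xist arrays (-0.22). Oxidative phosphorylation genes fell by 0.12 (camera adjusted p = 2.14e-04, and adjusted p = 0.896 with an estimated correlation). Their shift was -0.07 without control anti-miR replicate 4, and they did not pass on the 9 Xist arrays (-0.09).

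Interferon-stimulated genes rose by 0.33, with 15 of 16 higher (camera adjusted p = 0.00264, and adjusted p = 0.896 with an estimated correlation). The call was lost without control anti-miR replicates 1 (0.25) or 2 (0.21), without saline replicates 1 (0.27) or 2 (0.24) and on the 9 Xist arrays (0.17). The shift was 0.50 without control anti-miR replicate 3 and 0.53 without saline replicate 4. T cell markers rose by 0.54, with 8 of 8 higher (camera adjusted p = 0.00264, and adjusted p = 0.476 with an estimated correlation), a call lost without control anti-miR replicate 1 (0.29), with sex as a covariate (0.42) and on the 9 Xist arrays (0.28). Efflux and LXR genes differed by 0.00 and macrophage markers by 0.07, and neither list passed. Of M2-type genes Cd163 passed over the list alone, while the list mean (-0.16) and median (0.03) had opposite signs.

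Further genes low with control anti-miR were Dpyd (-2.09 ± 0.37), Gsta3 (-1.76 ± 0.39), Kcnj3 (-1.55 ± 0.32), Ryr1 (-1.33 ± 0.27), Efcab1 (-0.98 ± 0.20), Rnf32 (-0.71 ± 0.16) and Hadh (-0.36 ± 0.08). Those high with it were Ifi209 (1.49 ± 0.28), Zfp54 (1.40 ± 0.28), Spn (1.30 ± 0.32), Nrcam (1.26 ± 0.27), Shisa3 (1.25 ± 0.30), Socs3 (1.18 ± 0.29), a feedback inhibitor of cytokine signalling, Ptpn6 (0.87 ± 0.15), Igf2bp3 (0.85 ± 0.19), Galnt7 (0.68 ± 0.17) and Gpr174 (0.54 ± 0.13). Gpr174 lay at 2.36 to 3.20 on all arrays, as low as the Y-linked genes on Xist arrays, so its difference may be background. Igf2bp3, Efcab1, Rnf32, Zfp54, Nrcam and Shisa3 were below the median of all values, 6.90, on all arrays. In limma 0 probe sets passed the adjusted threshold. An unadjusted p under 0.05 was found for 1868, 888 higher and 980 lower, fewer than the 2255 that chance gives. Among the probe sets left without dim ones, 1225 had such a p. Camera called 6 of 32 lists, 3 up and 3 down, with 0 by an estimated correlation, 0 by fry, and exact p under 0.05 for 2 list means (0 after adjustment). The count was 10 without control anti-miR replicate 4 and 3 on the 9 Xist arrays.

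Anti-miR-33 against both control groups together set 4 arrays against 8. Averaged over both controls, T cell, M1-type and interferon genes were lower and smooth muscle, heart muscle and fatty acid oxidation genes higher with anti-miR-33. Smooth muscle differed by 0.43 from control anti-miR and 0.35 from saline, but the others differed less from saline. Heart muscle differed by 0.50 and 0.02, fatty acid oxidation by 0.37 and 0.09, and M1-type by -0.74 and -0.16. T cell markers differed by -1.02 and -0.48, and interferon genes by -0.59 and -0.26. T cell markers fell by 0.75 and M1-type genes by 0.45 (camera adjusted p = 6.9e-04 and 0.00105, against adjusted p = 0.415 and 0.355 with an estimated correlation). In each of them 3 members passed when adjusted over the list alone. Smooth muscle markers rose by 0.39 and fatty acid oxidation genes by 0.23 (camera adjusted p = 2.34e-05 and 1.06e-05, against adjusted p = 0.415 and 0.355 with an estimated correlation). The latter rise was 0.13 without anti-miR-33 replicate 3, and the former was 0.25 without anti-miR-33 replicate 1.

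Interferon-stimulated genes fell by 0.43, macrophage markers by 0.26, M2-type genes by 0.32 and efflux and LXR genes by 0.17, at camera adjusted p of 6.4e-04, 4.1e-04, 0.00882 and 0.0113. With an estimated correlation these were adjusted p = 0.488, 0.415, 0.525 and 0.423. Without anti-miR-33 replicate 4 the M2-type (-0.29) and efflux (-0.15) calls were lost, and the efflux call was lost on the 9 Xist arrays (-0.15). Adhesion genes and MHC class II genes fell by 0.28 each (camera adjusted p = 0.0138 and 0.017, against adjusted p = 0.355 and 0.57 with an estimated correlation). The adhesion call was lost without anti-miR-33 replicate 3 (-0.26) and with the mean of all probe sets of a gene (-0.17), and the MHC class II call without anti-miR-33 replicate 1 (-0.16) or control anti-miR replicate 2 (-0.19). Heart muscle markers rose by 0.26, fibroblast markers by 0.12 and oxidative phosphorylation genes by 0.09, at camera adjusted p of 4.18e-04, 0.0261 and 6.3e-05, against adjusted p = 0.423, 0.423 and 0.57 with an estimated correlation. Heart muscle markers shifted by 0.11 without anti-miR-33 replicate 3, 0.14 without saline replicate 4 and 0.42 on the 9 Xist arrays. The oxidative phosphorylation call was lost without anti-miR-33 replicate 3 (0.02). For fibroblast markers it was lost without anti-miR-33 replicates 2 (0.12) or 4 (0.07), without saline replicate 3 (0.10), without dim probe sets (0.12) and on the 9 Xist arrays (0.02).

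Pctp (-1.06 ± 0.18), a phosphatidylcholine transfer protein, Pkib (-0.82 ± 0.14) and Ptpre (-0.63 ± 0.11) were low with anti-miR-33 against the mean of both control groups, with Gpr18 (-1.55 ± 0.27), Ipcef1 (-1.11 ± 0.23), Cd8b1 (-1.09 ± 0.21), Sla (-0.73 ± 0.14), Ptpn6 (-0.72 ± 0.13), Basp1 (-0.39 ± 0.07) and Syt1 (-0.39 ± 0.08). Mlana (1.78 ± 0.36), Elavl1 (1.28 ± 0.29), Aif1l (1.25 ± 0.22), Vstm4 (1.07 ± 0.22), Zfp612 (0.98 ± 0.23), Wnt5b (0.91 ± 0.21), Prkaa2 (0.89 ± 0.21), Lgr6 (0.78 ± 0.18), Prkce (0.75 ± 0.16) and Mef2c (0.50 ± 0.12) were high. Syt1 lay at 3.52 to 4.11 on all arrays, about as low as the Y-linked genes on Xist arrays, so its difference may be background, and Cd8b1, Elavl1 and Aif1l were below 6.90 on all arrays. Abca1 differed by -0.12 ± 0.07 and Abcg1 by -0.20 ± 0.07. In limma 0 probe sets passed the adjusted threshold (smallest adjusted p 0.507). An unadjusted p under 0.05 was found for 2798, 1319 higher and 1479 lower, or 4616 with array weights, where chance gives 2255. Camera called 13 of 32 lists, 5 up and 8 down, with 0 by an estimated correlation, 0 by fry, and exact p under 0.05 for 5 list means (0 after adjustment).

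The comparisons share arrays, so their differences are related with no effect at all. Across all probe sets, which are not independent replicates, the differences of anti-miR-33 and of saline from control anti-miR correlated at 0.61, against 0.50 in 50 simulations of unchanged groups and 0.09 when the 4 control anti-miR arrays were split between the comparisons. Their covariance was 0.063 against a simulated 0.046, a difference of 0.017. From saline, the differences of anti-miR-33 and control anti-miR correlated at 0.35, against 0.50 simulated and -0.10 split, with a covariance of 0.031 against 0.047, a difference of -0.016. Anti-miR-33 against each control correlated at 0.54, against 0.50 simulated and 0.07 split, with a covariance of 0.053 against 0.047, a difference of 0.006. The simulations drew each probe set independently, while real probe sets vary together. They therefore do not show how far such correlations vary by chance, and the gaps do not show an effect beyond the shared arrays.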

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

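The tests for mixed RNA, for female mice, for the macrophage share and for sex balance, and the heart muscle covariate of 4 genes, were chosen after the results they bear on were seen.

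Sex-linked genes contradicted the label on 9 of 12 arrays. RNA of both sexes mixed on an array in amounts that bring both signals above the median of all values, 6.90, was excluded. On 0 arrays did Xist and the mean of the Y-linked genes both exceed it. A smaller share of RNA from the other sex could stay under that cut and is not excluded. A single misread Xist probe set was excluded too, as 3 of 3 Xist probe sets with signal separated the same arrays. For the brightest probe sets of Eif2s3y, Kdm5d and Uty, the highest value on these arrays was 4.10 and the lowest on the other 3 was 7.74, and each of 9 Y-linked probe sets separated the arrays the same way, which is what female mice under a male label would give. Exchange with samples from outside these 12 arrays could give it as well and was not tested.

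The M1-type, interferon and T cell lists were lower with anti-miR-33 than with control anti-miR. A lower share of macrophage RNA alone would not lower T cell markers while smooth muscle markers rise. The T cell list minus the smooth muscle list differed by -1.46 (SE 0.52), though both shifts were known when this contrast was chosen. Control anti-miR replicates 1 and 2 carried most of it, with T cell means of 9.66 and 9.41 and smooth muscle means of 10.76 and 10.78. Replicates 3 and 4 had 8.42 and 8.16, and 11.38 and 11.34. The anti-miR-33 arrays had 7.71 to 8.04 and 11.28 to 11.91. The contrast thus leans on 2 arrays, and smooth muscle means alone had an exact permutation p of 0.143. For the M1-type and interferon lists the contrast decides nothing. Macrophage markers fell by 0.29 as well, so a lower macrophage share stays open for these lists. With the T cell list mean as a covariate the M1-type difference was -0.58 (SE 0.22), against -0.74 (SE 0.16) without it. The list did not clearly follow the covariate (slope over SE 1.09), so T cell content stays open. The bound set beforehand for excluding it asked for no slope and was met. Without a slope the covariate cannot decide, so that bound was wrong. On the 9 Xist arrays the M1-type difference was -0.72 (SE 0.20), which excluded the sex balance of the groups as the cause. Effects of anti-miR-33 and of the control oligonucleotide also remain open, since the M1-type list also rose by 0.58 with control anti-miR against saline.

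Fatty acid oxidation and oxidative phosphorylation genes were higher with anti-miR-33 than with control anti-miR, together with heart muscle markers. With the muscle list mean as a covariate the fatty acid oxidation difference was 0.24 (SE 0.08), against 0.37 (SE 0.10) without it, but with the mean of Myh6, Myl7, Actc1 and Tnnt2 it was 0.15 (SE 0.11). The list mean includes Myl2 and Acta1, whose SD over the arrays was 1.13 and 1.09 and which did not move with the others, so the data cannot tell whether captured heart muscle could be the source. The oxidative phosphorylation difference was 0.04 (SE 0.07) with the muscle list mean and 0.02 (SE 0.12) with the 4 genes, but at 0.15 (SE 0.09) it lay within 2 SE of 0 without a covariate, so this test decides nothing. RNA degradation stays open too. Fatty acid oxidation differed by 0.35 (SE 0.11) with the Gapdh 3' minus 5' difference as a covariate. The list did not follow that covariate (slope over SE -0.64). The bound set beforehand for excluding degradation asked for no slope and was met, but without a slope the covariate cannot decide.

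The arrays were regrouped to see how often other groupings give counts as large. For anti-miR-33 against control anti-miR, the grouping by treatment alone of 35 gave as many as 14 lists past camera's threshold. That share lies under the bound set beforehand, but it is the smallest that 35 groupings can give. It was not adjusted for the other counts tested in this way, so it does not exclude a chance arrangement. The highest other count was 13, a margin of 1 list. The count by treatment was itself 13 with a second quantile normalisation and 0 with an estimated correlation. It was 11 without dim probe sets, where neutrophil markers had too few members left to be tested. The other groupings were not counted under these settings, so little rests on that margin. An unadjusted p under 0.05 was reached by as many probe sets in 7 of 35 groupings, with up to 7229 against 3328 by treatment. The grouping that reached 7229 exchanges anti-miR-33 replicate 4 with control anti-miR replicate 4 and had 30 probe sets past the adjusted threshold. That grouping is the most extreme of 35 and was picked after its counts were seen. It therefore cannot show a structure of the samples other than treatment, and none was tested.

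For anti-miR-33 against saline, counts as large as the 1848 probe sets and 3 lists by treatment were found in 14 and 26 of 35 groupings, with highest other counts of 4516 and 13. For control anti-miR against saline, counts as large as 1868 and 6 were found in 24 and 13 of 35, with highest other counts of 3995 and 14. For anti-miR-33 against both control groups, counts as large as 2798 and 13 were found in 18 and 5 of 100, with highest other counts of 4333 and 16. A chance arrangement is not excluded for any of these. Past the adjusted threshold the count by treatment was 0 in every comparison, so 35 of 35 groupings, or 100 of 100 with both control groups, were bound to give as many, and this tests nothing.

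In 21 of 324 groups of 4 arrays, 1 array lay far from its 3 neighbours, where chance gives about 16. Among list means, these were cholesterol synthesis on anti-miR-33 replicate 4 (9.14, others 8.87 to 8.91), lipid uptake on saline replicate 3 (12.09, others 12.62 to 12.72) and M2-type genes on control anti-miR replicate 4 (8.16, others 8.86 to 8.96). Interferon-stimulated genes on saline replicate 4 (9.31, others 8.45 to 8.59) and matrix remodelling on anti-miR-33 replicate 1 (11.39, others 11.44 to 11.45) were further ones. The 3' minus 5' difference of Actb was 1.81 on saline replicate 1, against 1.44 to 1.49.

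Among genes with anti-miR-33, Srebf2 was at 10.34 on replicate 4 (others 10.06 to 10.09) and Nrcam at 4.24 on replicate 2 (others 4.57 to 4.63). Replicate 3 stood apart for Tlr4 (10.19, others 11.21 to 11.25), Btbd19 (11.62, others 11.89 to 11.94) and Spn (8.04, others 8.81 to 8.84). With control anti-miR, Prkaa2 was at 9.22 on replicate 3 (others 8.49 to 8.59), while replicate 4 was low for Tnf (5.69, others 6.57 to 6.66) and Tlr4 (10.46, others 11.17 to 11.23). With saline, replicate 1 stood apart for Cpt1a (12.56, others 11.83 to 11.92) and Ncam1 (12.38, others 12.85 to 12.88), and replicate 2 for Hadh (13.16, others 12.95 to 12.98) and Lman2l (6.75, others 6.59 to 6.61). Rab3d was low on replicate 3 (3.49, others 3.97 to 4.06), and replicate 4 was high for Arg1 (7.72, others 5.88 to 6.19) and Shisa3 (4.60, others 3.95 to 4.04).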

How the results depend on the processing

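The covariate for expression-defined sex and the fit of the 9 Xist arrays were chosen after the results were seen. Of counts of lists 66 of 84 stayed within 1.5 times the reported count and 18 did not, and 89 of 91 counts of probe sets stayed at 0. Among list shifts 631 of 755 stayed past the threshold, 124 did not and 0 reversed, while of 2927 gene results 3 came to pass and 5 changed sign after moving by more than their SE, though each of the 5 then lay within its SE of 0. As no gene passed to begin with, the others staying short of the threshold says nothing of their stability.

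With an estimated correlation 0 lists passed for anti-miR-33 against control anti-miR, 0 against saline, 0 for control anti-miR against saline and 0 against both control groups. Fry gave 4, 0, 0 and 0. These tools allow for the correlation measured between list members.

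For anti-miR-33 against saline the count of 3 lists was 6 with the mean of all probe sets of a gene, 5 with sex as a covariate, 13 on the 9 Xist arrays, and 1 to 11 leaving out single arrays. For control anti-miR against saline the count of 6 was 3 on the 9 Xist arrays and 5 to 10 leaving out single arrays, and the count of 0 probe sets was 1 without dim probe sets and 0 to 2 leaving out single arrays. The cause was not tested.

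Leaving out single arrays, Crot ran from -0.39 to 0.00 for anti-miR-33 against control anti-miR and from -0.16 to 0.23 for control anti-miR against saline, so without control anti-miR replicate 1 the former difference vanished and the latter was -0.16. Tlr4 ran from -0.15 to 0.20 for anti-miR-33 against both control groups, with 0.20 without anti-miR-33 replicate 3. For control anti-miR against saline, Cpt1a was 0.13 on the 9 Xist arrays and Cd68 was -0.02 with sex as a covariate. The cause was not tested.

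With the replicate number as a block, 0 probe sets and 14, 3, 6 and 14 lists passed. After centring within groups, arrays of the same replicate number correlated at -0.05 on average (12 pairs) and others at 0.02 (36 pairs). This gave no sign that the numbers mark shared batches, but it cannot exclude them, as the pairs are few and not independent. The alternatives of the seed site test were not run, as that test was not. Dim probe sets, near the background of the arrays, limit which genes could show a difference.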

Other observations

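The gene sets tested in this part were chosen after the gene that led to each had been seen, and the expectations were written before the tests were run.

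The control anti-miR group stood apart from both other groups in several macrophage genes, and tissue-resident macrophages offered 1 explanation. Cxcl13, Cd163 and Vsig4, genes of resident macrophages in several tissues, were lowest with control anti-miR. A mean of 11 other resident macrophage genes was 8.96 ± 0.20 with control anti-miR and 9.34 ± 0.12 with saline (-0.38, exact permutation p = 0.0286), the difference that fewer such cells predict. Cd209f (-1.14), Lyve1 (-1.07), F13a1 (-0.78), Timd4 (-0.55), Pf4 (-0.43) and Cbr2 (-0.36) were lower. Cd209d (0.04), Gas6 (-0.02), Stab1 (0.02) and Mrc1 (-0.08) differed little and Folr2 (0.16) was higher. In every group Cd209f, Timd4 and Cd209d had means below the median of all values, 6.90, so their differences may partly be background. Lower expression of some of the 11 genes in the same cells also stays open. The mean was also lower with anti-miR-33 than with saline (-0.28, exact p = 0.0286), so the loss may belong to both oligonucleotides and not to the control alone. Between anti-miR-33 and control anti-miR it differed by 0.10, so this set did not set control anti-miR apart from anti-miR-33 as Cxcl13 and Cd163 did. Saline had 2 arrays with Y-linked signal and control anti-miR 0, and the set was not compared on Xist arrays alone. Of the 11 genes, 4 are also on the M2-type list, so the sets overlap.

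Mlana was higher with anti-miR-33 than with control anti-miR, and more pigment cells in the captured tissue might explain it. The mean of 8 other pigment cell genes was 6.68 ± 0.71 with anti-miR-33 and 5.93 ± 0.25 with control anti-miR (0.74, exact permutation p = 0.0857), with Dct (1.43), Tyrp1 (1.11) and Tyr (0.96) highest. Trpm1 (0.93), Slc45a2 (0.92) and Pmel (0.52) were higher too, while Sox10 (0.02) and Oca2 (0.07) differed little. Apart from Dct and Tyrp1, these genes had means below the median of all values, 6.90, in both groups. Their differences may therefore partly be background. The data cannot tell, since a p that misses the threshold excludes nothing, and the expectation written beforehand was wrong to count it as evidence against.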
